A study of Mus musculus with 44 samples.

How the data were processed

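The series profiled RNA of liver nuclei from male mice of a line in which hepatocyte nuclei carry a tag for immunoprecipitation. INTACT is this isolation of nuclei tagged in specific cell types. Per the labels, 22 mice gave 1 library of tagged hepatocyte nuclei and 1 library of whole liver nuclei each, 44 libraries in all. The mice had received the FPC diet for 20 weeks, the choline-deficient, amino acid-defined, high-fat diet (CDAHFD) for 7 weeks, or a low-fat control diet for the same periods. Mice on either diet that induces non-alcoholic steatohepatitis (NASH) were sorted by liver histology into mild and advanced disease, per the series design. These 2 groups were therefore not randomised. The labels do not say which promoter drives the tag.

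Per the labels' protocols, total nuclear RNA (50 to 100 ng) went into a stranded library kit without selection for poly-adenylated RNA, and both ends of each fragment were read for 50 bases on an Illumina HiSeq. Per the submitters' processing notes, STAR 2.4.2a, DESeq2 1.24.0 and the mouse build mm10 were used. The tool that counted reads and its strand setting are not stated. The authors deposited raw counts, which are whole numbers for each library and 20105 RefSeq transcript identifiers. They also deposited a table of log2 fold changes between groups of hepatocyte libraries, per the file headers. The same deposited table holds the adjusted p-value of each of those comparisons. It covers 13147 genes and gives positions and lengths, and for 94.7% of them the counted length equals the length of the whole gene, so introns were counted with exons. All 20105 identifiers are those of protein-coding transcripts. No mitochondrial genes, Malat1 or Neat1 are among them, so the planned shares of mitochondrial and nuclear-retained RNA could not be computed. Symbols came from the authors' table for 13147 identifiers and from a RefSeq gene table for 6879. The other 82 have no symbol. Reads of near-identical gene copies (the Mup, Cyp2, Hsd3b, Gsta, Sult2a and Vmn2r families) and of genes that overlap in their bodies could have been divided between them or counted for both, so values of these genes are uncertain.

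Library totals ran from 12.1 to 33.1 M counts with a median of 22.8 M. Replicates differed by more than sampling noise (chi-square per degree of freedom 20.9 to 290.03 between pairs of libraries of a group), and the spread between mice, not counting error, sets the precision. CPM values, counts scaled to a common library total, were computed here from the deposited counts. Intervals and floors given for genes with 0 to 3 counts in a group cover counting error only. The floor is 3 counts over the group, and intervals are 95% intervals of the ratio of counts.

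Differences between groups were tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1): trimmed-mean (TMM) scaling, the default expression filter, a robust quasi-likelihood fit and its F-test, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. The 11 libraries of a fraction and diet were fitted together, and the 22 libraries of a diet for comparisons of the fractions. The 22 hepatocyte libraries were fitted together for the difference between diets, taken as the CDAHFD change minus the FPC change. Animal numbers in the labels pair the fractions of a mouse. Over 10324 genes, deviations from the group mean correlated by more than 0.1 between both libraries of 20 of the 22 mice, and most highly with the mouse's own partner in the same 20. Fits with the mouse as a block are given where they change a count by more than 1.5-fold.

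The comparisons, the alternatives, 25 pathway lists, 9 lists of cell type markers and the rule for naming genes were fixed before the data were examined, except where the text says otherwise. Of the 571 genes in the lists, 567 had a measured identifier (H19, Mx1, Serpina4-ps1 and Clock had none). The pathway lists are cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, lipid droplets and uptake, bile acids, xenobiotic cytochromes P450, urea cycle with gluconeogenesis and amino acids, complement and coagulation, acute phase, collagen and matrix, YAP targets, fetal and progenitor-associated genes, hepatocyte transcription factors, interferon response, NF-kB targets, the unfolded protein and integrated stress response, NRF2 targets, p53 targets, cell cycle, pericentral, periportal, male-biased and female-biased liver genes, circadian clock and immediate early genes. The marker lists are hepatocyte, stellate cell, endothelial, Kupffer cell, recruited macrophage, lymphocyte, neutrophil, cholangiocyte and mesothelial. List counts are given over all genes tested and, where they differ, adjusted over the list alone. Lists with at least 3 measured genes were also tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated from the data.

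Named genes are the largest changes in each direction among genes past the threshold, with a mean of at least 5 CPM in a compared group and groups that do not overlap. There are 5 per direction for advanced against control hepatocyte nuclei, 3 in whole liver and 2 elsewhere. Added to these are the 2 members of each list with the lowest p and 20 fixed genes. Elf3 and Glis2 are among the fixed genes because they are remembered from the study itself, so they are not independent picks. Carry-over is the median over endothelial markers of a mouse's hepatocyte CPM divided by its whole liver CPM. An alternative that subtracts the whole liver profile times this ratio was chosen after seeing the data. The other alternatives were DESeq2 1.42.0, RLE scaling, no expression filter, a stricter filter of 1 CPM, the libraries of the compared groups alone, the mouse as a block and leaving out each mouse. Exact permutation tests and rank statistics used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.

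The edgeR step was tested on simulated data with 200 changed genes among the real genes. For advanced against control hepatocyte nuclei under FPC (13498 genes), it recovered 7.14% of 1.5-fold, 51.9% of 2-fold and 90.3% of 4-fold changes, and 4.26% of its calls were false. For advanced against mild under CDAHFD (13277 genes) recovery was 14.1%, 50.7% and 90.5%. For the difference between diets (13808 genes) it was 2.90%, 35.0% and 83.1%. For the fractions in FPC controls (14333 genes) it was 31.3%, 69.4% and 88.7%, and for the CDAHFD interaction of fraction and disease (14315 genes) 1.39%, 29.9% and 68.9%. Each simulation changed 200 genes, while 6336 were called in the real comparison of advanced and control FPC hepatocyte nuclei. More calls make the adjusted threshold less strict, so these recoveries do not give the sensitivity of that comparison.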

Results

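Nuclear RNA was compared between hepatocytes and whole liver of the same male mice, and between healthy and steatohepatitic livers under 2 diets. Each diet study held 4 control, 4 mild and 3 advanced mice, and each mouse gave a library of tagged hepatocyte nuclei and a library of whole liver nuclei. Library totals ran from 12.1 to 33.1 M counts, and the hepatocyte libraries of advanced CDAHFD mice were the smallest (mean 15.6 ± 5.44 M). None of 150 two-sided exact permutation tests of library measures between groups passed after Benjamini-Hochberg adjustment (smallest adjusted p = 0.0516, where 4 against 3 mice cannot give an unadjusted p under 0.0286). Many measures reached that smallest p, with groups that did not overlap. Recruited macrophage markers in FPC hepatocyte nuclei, for example, had mean log2 values of 2.06 in advanced and -0.26 in control mice. The adjusted tests therefore do not show that library measures were alike between groups. For single genes, adjusted p-values are Benjamini-Hochberg values of edgeR's quasi-likelihood F-test, values after ± are standard errors for log2 fold changes and SD for CPM, and genes called changed have an adjusted p under 0.05. For gene lists, the value after the median is the camera adjusted p with the preset correlation between genes, followed by the adjusted p with an estimated correlation where the call rests on it. Mice are named by group and animal number.

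In control livers, RNA of sinusoidal, mesenchymal and immune cells was much lower in tagged hepatocyte nuclei than in whole liver nuclei. Stab2, a scavenger receptor of liver endothelium, fell from 456.5 ± 66.8 CPM in whole liver to 39.3 ± 7.34 CPM in hepatocyte nuclei of FPC controls (log2 fold change -3.38 ± 0.18, adjusted p = 5e-11). The endothelial receptor Kdr was lower by -3.22 ± 0.19 (8.6e-11). The macrophage receptors Csf1r (-3.23 ± 0.23) and Adgre1 (-3.60 ± 0.35), the pericyte genes Pdgfrb (-2.88 ± 0.21) and Rgs5 (-3.06 ± 0.22) were lower too. So were the B cell factor Pax5 (-3.63 ± 0.25), the T cell kinase Lck (-3.24 ± 0.35), the neutrophil receptor Csf3r (-3.43 ± 0.38) and the mesothelial factor Wt1 (-4.33 ± 0.51). All 18 endothelial markers fell (median -3.22, camera adjusted p = 1.7e-21, p = 0.037 with estimated correlation), as did all 14 stellate cell markers (median -2.75, 9.7e-13, and 0.024 with an estimated correlation). Lower too were 12 of 13 Kupffer cell markers (median -3.23, 5.8e-10, p = 0.055 with estimated correlation). Lymphocyte markers fell in 14 of 18 (15 adjusted over the list alone; median -3.24, or -3.18 with genes at 0 counts set to their bound; 4.3e-10, p = 0.055 with estimated correlation). Collagen and matrix genes fell in 26 of 33 (27 over the list alone; median -2.61, 1.4e-17, p = 0.024 with estimated correlation). Of 4 mesothelial markers 2 fell (3 over the list alone; median -1.72, 0.0088, p = 0.037 with estimated correlation), and of 3 neutrophil markers 1 (2 over the list alone; median -2.65, 0.057).

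Cholangiocyte markers were retained more than these: in FPC controls 3 of 12 fell (median -0.76, camera adjusted p = 0.12, and 0.045 with the mouse as a block). Bicc1 and Glis3, both active in biliary epithelium, were lower by -0.92 ± 0.15 (6.7e-05) and -0.84 ± 0.15 (0.00023). None of the 22 hepatocyte markers passed the test (median 0.21, 0.12, and 0.0048 with the block). The prothrombin gene F2 and the antithrombin gene Serpinc1 stood at 0.25 ± 0.11 (0.13) and 0.31 ± 0.13 (0.14), and with the mouse as a block at adjusted p = 0.002 and 0.00014. Controls of the CDAHFD study gave similar values: all 18 endothelial markers (median -3.54, 9.7e-22), 12 of 13 Kupffer cell markers (median -3.63) and 4 of 12 cholangiocyte markers (5 over the list alone; median -1.09, 0.13, and 0.010 with the block) fell. Adgre1 was lower by -4.54 ± 0.18 (1.3e-13), the T cell factor Bcl11b by -5.11 and the stellate cell ligand Hgf by -3.48. Altogether 193 genes were higher and 2319 lower in hepatocyte than in whole liver nuclei of FPC controls (14333 tested), and 2092 higher and 2352 lower in CDAHFD controls (14315 tested). The number of higher genes depends on the fit. In FPC controls it was 632 against 1942 lower with the stricter filter and 3069 against 2698 with the mouse as a block. It depends on scaling too, with 340 higher and 2432 lower by RLE in CDAHFD controls and 471 and 2592 by DESeq2. The median log2 ratio of all genes there is 0.20 with TMM and 0.06 with RLE. Among genes changed at least 2-fold, 2 and 13 were higher against 2150 and 2184 lower. With the mouse as a block, 5767 and 6186 genes were called in all, 3712 higher and 2474 lower of them in CDAHFD controls. Libraries of Control_9862 and Control_9867 deviate crosswise from their labelled pairs, and exchanging them raises the blocked CDAHFD count (given below).

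Endothelial markers served as the measure of carry-over. Their hepatocyte to whole liver ratio was 9.27 ± 1.09% in FPC controls, 17.0 ± 5.20% in FPC mild mice (24.4% in mouse Mild_6825) and 9.11 ± 2.18% in FPC advanced mice. It was 7.16 ± 1.59%, 7.60 ± 0.501% and 8.12 ± 0.916% in the CDAHFD groups. Subtracting this share of the whole liver profile, called the carry-over correction below, was chosen after seeing the data. It is given beside each list in the text whose number of changed genes it moved by over 2, and beside some others, but not for endothelial markers, which define it. Counts after it cover the genes that still had enough counts to test. Where calls were lost, medians and median standard errors before and after are over these same genes.

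**Figure D1:**
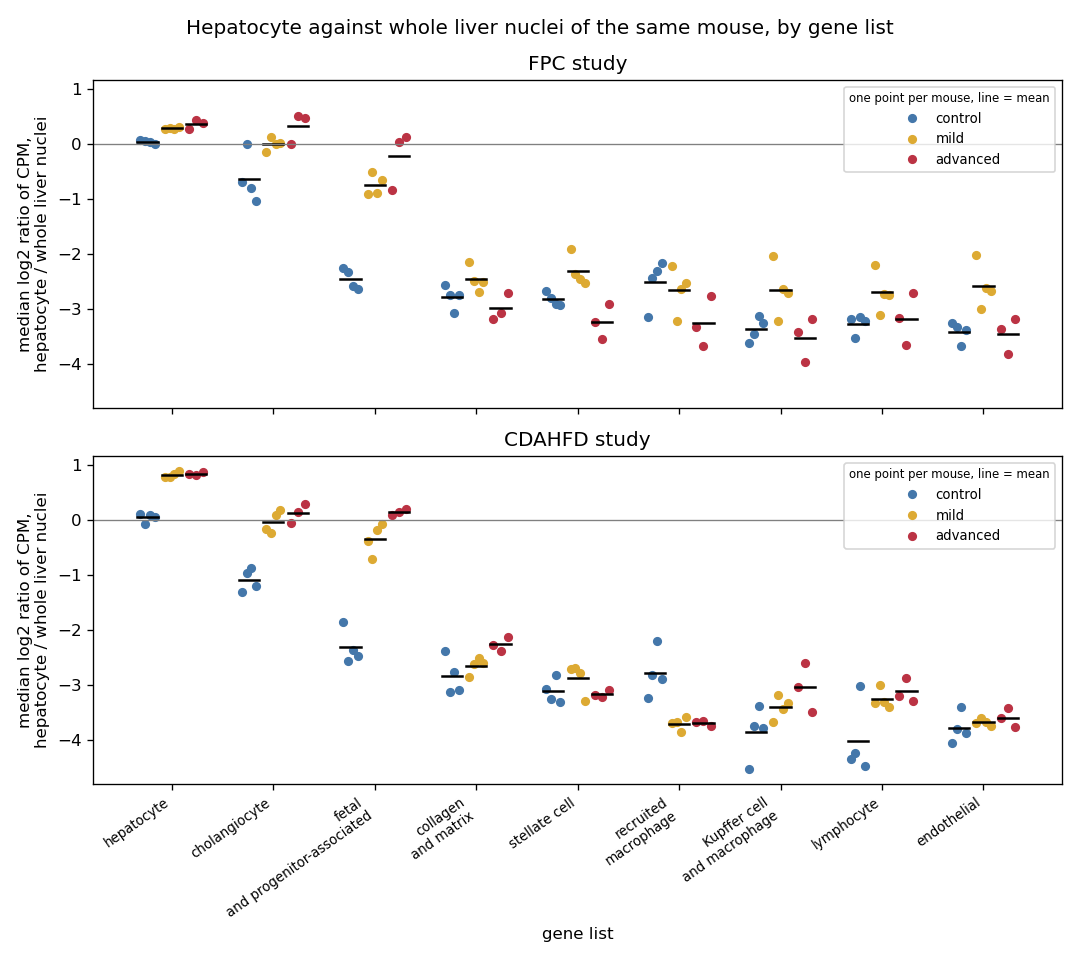
Median log2 ratio of CPM, hepatocyte over whole liver nuclei of the same mouse (vertical axis, log2), for 9 gene lists (horizontal axis) in the FPC and CDAHFD studies, with 1 point per mouse, a line at the group mean and colours for control, mild and advanced. Endothelial ratios lie near -3.42 in FPC controls, and cholangiocyte ratios move from -0.64 in FPC controls to 0.32 in FPC advanced mice.

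In hepatocyte nuclei under FPC, Spp1, the secreted phosphoprotein osteopontin, rose from 1.61 ± 0.567 CPM in controls through 12.9 ± 1.38 in mild to 63.7 ± 12.9 in advanced mice (log2 fold change 4.90 ± 0.23, adjusted p = 7.7e-09). The largest rises were those of the matrix protease Mmp7 (at least 434-fold, 0 counts in controls) and the vomeronasal receptor Vmn2r3 (601-fold, 95% counting interval 205 to 2920). Next came the RNA-binding protein Rbm24 (581-fold, 160 to 4800), Scube3 (8.38 ± 0.81, 4e-06) and the calcium channel Cacna1b (408-fold, 112 to 3370). Without mouse Advanced_6880 the log2 fold change of Vmn2r3 went from 8.79 to 7.51. The largest falls were in the male-specific hydroxysteroid dehydrogenase Hsd3b5 (447.8 ± 154 to 0.478 ± 0.218 CPM, log2 fold change -10.35 ± 0.65, 1.3e-07) and the urinary protein genes Mup12 (-7.99 ± 0.87) and Mup1 (-6.47 ± 0.79), with Lect1 (-7.22 ± 0.49) and Lrtm1 (-6.60 ± 0.58). Among fixed genes, the transcription factors Elf3 (4.20 ± 0.54, 3.4e-05), Glis2 (4.90 ± 0.41, 7.8e-07) and Sox9 (1.61 ± 0.37, 0.0032) rose. So did the cell cycle inhibitor Cdkn1a (5.15 ± 0.39), the hormone Fgf21 (4.91 ± 0.68), Lcn2 (6.41 ± 0.59), the fatty acid transporter Cd36 (1.98 ± 0.53, 0.011) and Col1a1 (3.76 ± 0.31, 6.5e-07). Hnf4a, a main regulator of hepatocyte identity, fell (-0.81 ± 0.16, 0.00098), as did Cyp8b1, which sets the cholic acid share of bile acids (-3.23 ± 0.41, 3.7e-05). In all 3577 genes rose and 2759 fell among 13498, and 2849 and 922 of these by at least 2-fold.

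Several fixed genes stood near the threshold or did not pass it in this comparison. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had a log2 fold change of -0.02 ± 0.57 (adjusted p = 0.98), and the lipid droplet protein Plin2 -0.11 ± 0.23 (0.73). The Kupffer cell receptor Clec4f stood at -1.30 ± 0.59 (0.091; 0.037 with DESeq2 and 0.032 without mouse Advanced_6826). The stress hormone Gdf15 stood at 1.09 ± 0.45 (0.063; 0.032 with DESeq2, 0.043 with the libraries of both groups alone and 0.0082 without mouse Advanced_6826). The fetal gene Afp rose by 1.35 ± 0.36 (0.0081; 0.057 without mouse Advanced_6826), and the Kupffer cell receptor Timd4 fell (-2.09 ± 0.76, 0.038; lost without any of 5 mice, up to 0.121 without mouse Advanced_6880). Trem2, a receptor of lipid-associated macrophages, had 0 counts in controls and was at least 19.3-fold higher. Pdgfra, a stellate cell receptor, rose by 2.44 ± 0.31 (3.3e-05), and with the carry-over correction had 1.07 ± 1.07 (0.469). With the same correction Col1a1 had 3.62 ± 1.60 (0.094), a similar fold with a larger standard error, so a rise beyond carry-over was not shown.

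The gene lists that rose in advanced FPC hepatocyte nuclei by the camera test with the preset correlation are given here, and several did not pass with an estimated one. All 19 fetal and progenitor-associated genes rose (median 4.46, camera adjusted p = 9.8e-11, p = 0.031 with estimated correlation), among them the membrane-binding protein Anxa2 (5.41 ± 0.28), and 18 of 18 did so after the carry-over correction. All 11 cholangiocyte markers rose before and after the correction (median 4.95, 2.3e-08, p = 0.092 with estimated correlation). Bicc1 went from 18.5 ± 2.87 to 892.5 ± 233 CPM. Krt19, Krt7, Epcam, Sox9 and Spp1 belong to both lists. In the cell cycle list 19 of 20 rose (median 2.72, 2.3e-08, p = 0.031 with estimated correlation; 19 after correction), including the topoisomerase Top2a (4.55 ± 0.31) and the spindle protein Tpx2 (4.33 ± 0.36). In the collagen and matrix list 27 of 31 rose and 1 fell (29 and 1 over the list alone; median 2.14, 2.3e-08, p = 0.055 with estimated correlation), including Timp2 (4.36 ± 0.33). After the correction 9 of 23 rose, against 20 of the same genes before it. Their median went from 2.09 to 1.82 and their median standard error from 0.31 to 1.09. The subtraction takes away counts, which can widen errors, so these values do not tell a rise in hepatocytes from carried-over RNA. Hepatocyte to whole liver log2 ratios of the list were -3.19 to -2.72 in these mice, beside -3.83 to -3.18 for endothelial markers. Of 16 YAP targets 11 rose and 1 fell (median 2.0, 0.00012, p = 0.051 with estimated correlation; 10 of 15 after correction), with Ankrd1 at 6.12 ± 0.45 and Arhgef17 at 4.73 ± 0.30. Of 13 NF-kB targets 9 rose (11 over the list alone; median 2.41, 4.5e-05, p = 0.10 with estimated correlation; 7 of 10 after correction), with Relb at 4.65 ± 0.23 and the adhesion receptor Vcam1 at 4.70 ± 0.34. Interferon response genes (7 of 18, median 0.83, 0.028, p = 0.53 with estimated correlation) rose with smaller values. So did p53 targets (5 of 11, 6 over the list alone, 1 fell; median 1.09, 0.042, p = 0.10 with estimated correlation).

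Immune markers were measurable in the same libraries, where the endothelial carry-over ratio was 9.11%. All 10 recruited macrophage markers rose (median 4.81, 4.45 with genes at 0 counts set to their bound; camera adjusted p = 4e-06, p = 0.066 with estimated correlation), and after the carry-over correction 2 of 4 measurable ones (all 4 before; median 2.90 to 2.70, median standard error 0.36 to 0.91). Lymphocyte markers rose in 6 of 10 (median 2.0, 0.028, p = 0.47 with estimated correlation), and the 1 measurable after correction rose. Stellate cell markers (6 rose, 1 fell of 14; median 0.39, 0.15; 1 and 2 of 9 after correction, 5 and 1 of the same genes before, median 0.94 to -0.093, median standard error 0.31 to 0.89) passed no list test. Nor did endothelial markers (3 and 3 of 18, 3 and 1 over the list alone; median -0.32, mean 0.04, 0.53) or Kupffer cell markers (5 and 3 of 13; median 0.11, mean -0.07, 0.92; 1 rose of 3 after correction and 2 of these before, median 0.99 to 4.17, median standard error 0.34 to 1.41).

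Lists of hepatocyte function fell in advanced FPC mice. All 24 cholesterol synthesis genes fell (median -1.77, camera adjusted p = 1.7e-11, p = 0.10 with estimated correlation), before and after the carry-over correction. Among them were the sterol oxidase Msmo1 (144.1 ± 39.4 to 18.6 ± 5.96 CPM; -3.34 ± 0.28, 8.7e-07) and the sterol carrier Stard4 (-1.90 ± 0.16). Complement and coagulation genes fell in 22 of 26 (median -1.12, 1.4e-07, p = 0.0095 with estimated correlation), such as F13b (-1.57 ± 0.15). Bile acid genes fell in 16 of 19 (median -1.34, 1.1e-06, p = 0.055 with estimated correlation), such as the ligase Slc27a5 (-2.39 ± 0.20). Urea cycle, gluconeogenesis and amino acid genes fell in 14 of 21 (15 over the list alone; median -1.64, 1.1e-06, p = 0.10 with estimated correlation), such as the glutaminase Gls2 (-2.20 ± 0.18). Hepatocyte markers fell in 17 of 22 (18 over the list alone; median -1.02, 5.2e-06, p = 0.051 with estimated correlation). Hepatocyte transcription factors fell in 14 of 20 with 1 higher (median -0.82, 0.00045, p = 0.055 with estimated correlation). Xenobiotic cytochromes P450 fell in 9 of 15 (10 over the list alone; median -1.33, 0.0001, p = 0.031 with estimated correlation), including Cyp1a2 (-3.12 ± 0.36). Male-biased genes fell in 9 of 12 (10 over the list alone; median -3.17, 9.1e-06, p = 0.10 with estimated correlation). Pericentral genes fell in 7 of 12 (8 over the list alone; median -1.40, 0.00047, p = 0.24 with estimated correlation) and periportal genes in 6 of 12 (median -1.23, 0.0043, p = 0.10 with estimated correlation). Circadian clock genes fell in 8 of 15 (median -0.99, 0.013, p = 0.10 with estimated correlation).

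The remaining lists passed no camera test in advanced FPC hepatocyte nuclei. These were fatty acid synthesis (3 rose, 4 fell of 15; median -0.72, adjusted p = 0.058) and fatty acid oxidation (3 and 5 of 19; median -0.12, mean 0.36, tested as lower, 0.31). Lipid droplet and uptake genes (7 and 2 of 18; median 0.43, 0.18) and acute phase genes (9 and 2 of 20, 9 and 3 over the list alone; median 0.53, 0.18) did not pass, nor did NRF2 targets (9 and 1 of 15; median 1.18, 0.076). The last were the unfolded protein and integrated stress response (1 and 4 of 15, 1 and 3 over the list alone; median -0.14, 0.31), female-biased genes (3 and 0 of 9, 2 over the list alone; median 0.40, 0.31) and immediate early genes (4 and 0 of 11; median 2.04, 0.18). Single members still moved far: the lipid droplet protein Cidec rose by 5.11 ± 0.41 and the lipase Lpl by 4.95 ± 0.29. The cystine transporter Slc7a11 rose 450-fold (80.2 to 17800) and the exporter Abcc4 by 4.98 ± 0.48, while Acss2 (-2.64 ± 0.38) and the stress factor Atf4 (-0.89 ± 0.20, 0.0024) fell.

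In advanced CDAHFD hepatocyte nuclei Spp1 rose from 1.67 ± 0.771 to 34.7 ± 10.4 CPM (log2 fold change 3.92 ± 0.45, adjusted p = 2.5e-05), Elf3 by 4.74 ± 0.52 (1.4e-05) and Glis2 by 4.55 ± 0.49 (1.3e-05). Largest were the rises of Rbm24 (at least 494-fold, 0 counts in controls), Vmn2r3 (10.17 ± 0.70), Mmp7 (at least 306-fold) and Igdcc4 (8.51 ± 0.80). The macrophage and melanosome glycoprotein Gpnmb rose by 8.49 ± 0.52 and was too low to test after the carry-over correction. Largest falls were those of Moxd1 (1080-fold, 369 to 5230, with controls at 60.6 ± 100 CPM) and Hsd3b5 (518.2 ± 247 to 0.733 ± 0.107 CPM, -9.95 ± 0.95). Mouse Control_9867 held 5938 of the 6702 control counts of Moxd1, and without it the log2 fold change of Moxd1 went from -10.2 to -7.74. Next came Mup12 (-8.76 ± 0.68), the peptidase Trhde (-8.61 ± 0.43, 1.1e-07) and Lect1 (192-fold, 34.2 to 7580). Cdkn1a (4.09 ± 0.42), Fgf21 (3.59 ± 0.67), Lcn2 (7.53 ± 0.45), Cd36 (4.19 ± 0.38), Sox9 (1.94 ± 0.36), Col1a1 (3.03 ± 0.33), Pdgfra (1.73 ± 0.34, 0.001; 1.235 ± 0.71, 0.159 after the correction) and Trem2 (101-fold, 33.8 to 495) rose. Hnf4a (-0.74 ± 0.19, 0.006), Cyp8b1 (-2.21 ± 0.44) and Timd4 (-3.94 ± 0.75) fell. Cyp7a1 rose by 1.43 ± 0.52 (0.035; 0.064 without the expression filter, and lost without any of 6 mice, up to 0.12). Clec4f (0.06 ± 0.46), Plin2 (0.22 ± 0.38), Afp (0.86 ± 0.49, 0.15) and Gdf15 (1.05 ± 0.59, 0.14; 0.023 without mouse Control_10110) did not pass. In all 4028 genes rose and 3875 fell among 13277, and 2731 and 1484 of these by at least 2-fold.

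By list, most rises in advanced CDAHFD hepatocyte nuclei passed with the preset correlation alone. Cell cycle genes rose in 19 of 20 (median 3.72, camera adjusted p = 2.6e-09, p = 0.099 with estimated correlation), with the proliferation marker Mki67 at 8.29 ± 0.43. Fetal and progenitor-associated genes rose in 17 of 18 (median 4.05, 1.9e-08, p = 0.099 with estimated correlation; 15 of 17 after correction), with Anxa2 at 5.83 ± 0.30 and the hyaluronan receptor Cd44 at 3.57 ± 0.20. Cholangiocyte markers rose in 11 of 12 before and after correction (median 4.23, 5e-05, p = 0.26 with estimated correlation). NF-kB targets rose in 14 of 15 (median 3.40, 1.2e-06, p = 0.099 with estimated correlation). Collagen and matrix genes rose in 22 of 30 with 2 lower (median 1.75, 3.6e-05, p = 0.12 with estimated correlation). After the correction 13 of 25 rose, against 18 of the same genes before, while their median went from 1.76 to 2.06 and their median standard error from 0.33 to 0.56. YAP targets rose in 11 of 16 with 1 lower (median 1.91, 0.0029, p = 0.099 with estimated correlation), with Ankrd1 497-fold higher (170 to 2420). NRF2 targets rose in 12 of 15 with 1 lower (median 1.99, 0.00038, p = 0.12 with estimated correlation), led by the glutathione transferase Gsta1 (7.70 ± 0.60). Immediate early genes rose in 8 of 11 (median 2.97, 0.0071, p = 0.37 with estimated correlation) and female-biased genes in 5 of 9 (median 2.01, 0.026, p = 0.38 with estimated correlation). Acute phase genes rose in 9 of 21 with 2 lower (median 0.94, 0.028, p = 0.12 with estimated correlation) and p53 targets in 8 of 11 with 1 lower (median 1.05, 0.014, p = 0.26 with estimated correlation). Interferon response genes rose in 10 of 19 (8 over the list alone; median 0.79, 0.026, p = 0.53 with estimated correlation). At a carry-over ratio of 8.12%, all 10 recruited macrophage markers rose (median 4.48, 1.2e-05, p = 0.034 with estimated correlation; 3 rose and 1 fell of 4 measurable after correction, all 4 rose before, median 2.96 to 2.75, median standard error 0.31 to 0.89). So did 7 of 13 Kupffer cell markers with 2 lower (median 1.42, 0.040, p = 0.38 with estimated correlation) and 6 of 9 lymphocyte markers (median 2.03, 0.014, p = 0.31 with estimated correlation; 2 of 3 after correction, all 3 before, median 2.92 to 3.86, median standard error 0.43 to 1.08).

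**Figure D2:**
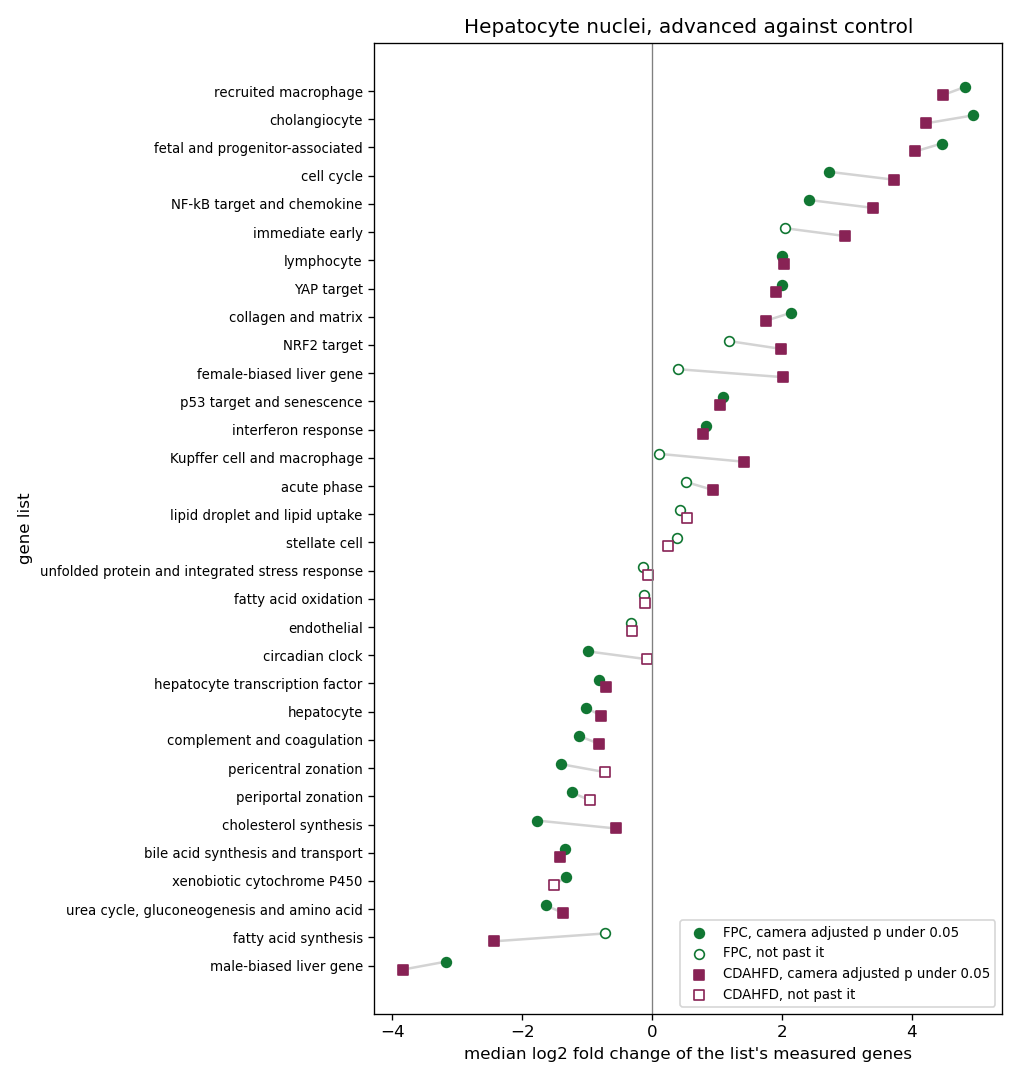
Median log2 fold change of each gene list (vertical axis) in hepatocyte nuclei, advanced against control (horizontal axis, log2), with green circles for FPC and purple squares for CDAHFD, filled where the camera adjusted p is under 0.05, and a grey line that joins both diets. Cholesterol synthesis lies at -1.77 under FPC and -0.55 under CDAHFD, fatty acid synthesis at -0.72 and -2.44.

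Among falling lists in advanced CDAHFD mice, all 15 fatty acid synthesis genes fell (median -2.44, camera adjusted p = 6.9e-06, p = 0.099 with estimated correlation; 14 after the carry-over correction). The elongase Elovl6 fell from 778.9 ± 275 to 55.5 ± 16.0 CPM (-4.31 ± 0.39) and Acss2, which makes acetyl-CoA from acetate, by -1.98 ± 0.16. Male-biased genes fell in 10 of 12 (median -3.83, 5e-05, p = 0.091 with estimated correlation), with the organic anion transporter Slco1a1 at -6.91 ± 0.37. Bile acid genes fell in 16 of 19 with 1 higher (median -1.42, 2.6e-05, p = 0.099 with estimated correlation). Complement and coagulation genes fell in 15 of 26 with 1 higher (2 over the list alone; median -0.81, 0.00098, p = 0.17 with estimated correlation). Urea cycle, gluconeogenesis and amino acid genes fell in 13 of 20 (median -1.37, 0.0022, p = 0.38 with estimated correlation), with the ornithine enzyme Otc at -2.35 ± 0.20. Hepatocyte transcription factors fell in 11 of 20 with 2 higher (median -0.70, 0.0082, p = 0.26 with estimated correlation), with the thyroid hormone receptor Thrb at -1.86 ± 0.14. Hepatocyte markers fell in 11 of 22 (median -0.78, 0.014, p = 0.28 with estimated correlation). Cholesterol synthesis genes fell in 10 of 24 (9 over the list alone; median -0.55, 0.015, p = 0.50 with estimated correlation). No camera test passed for cytochromes P450 (3 rose, 9 fell of 14; median -1.51, 0.084), lipid droplets (8 and 1 of 17; median 0.54, 0.074), pericentral (2 and 6 of 12; median -0.73, 0.16) or periportal genes (2 and 7 of 12; median -0.96, 0.13). The same applies to clock (1 and 3 of 15, 0 and 2 over the list alone; median -0.08, mean 0.02, 0.67) and stress response genes (4 and 2 of 15, 4 and 0 over the list alone; median -0.06, mean 0.43, 0.53). It applies too to fatty acid oxidation (4 and 6 of 19; median -0.10, mean 0.30, 0.67), stellate cell (4 and 2 of 12; median 0.24, 0.32) and endothelial (2 and 3 of 18; median -0.31, 0.59) lists.

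**Figure D3:**
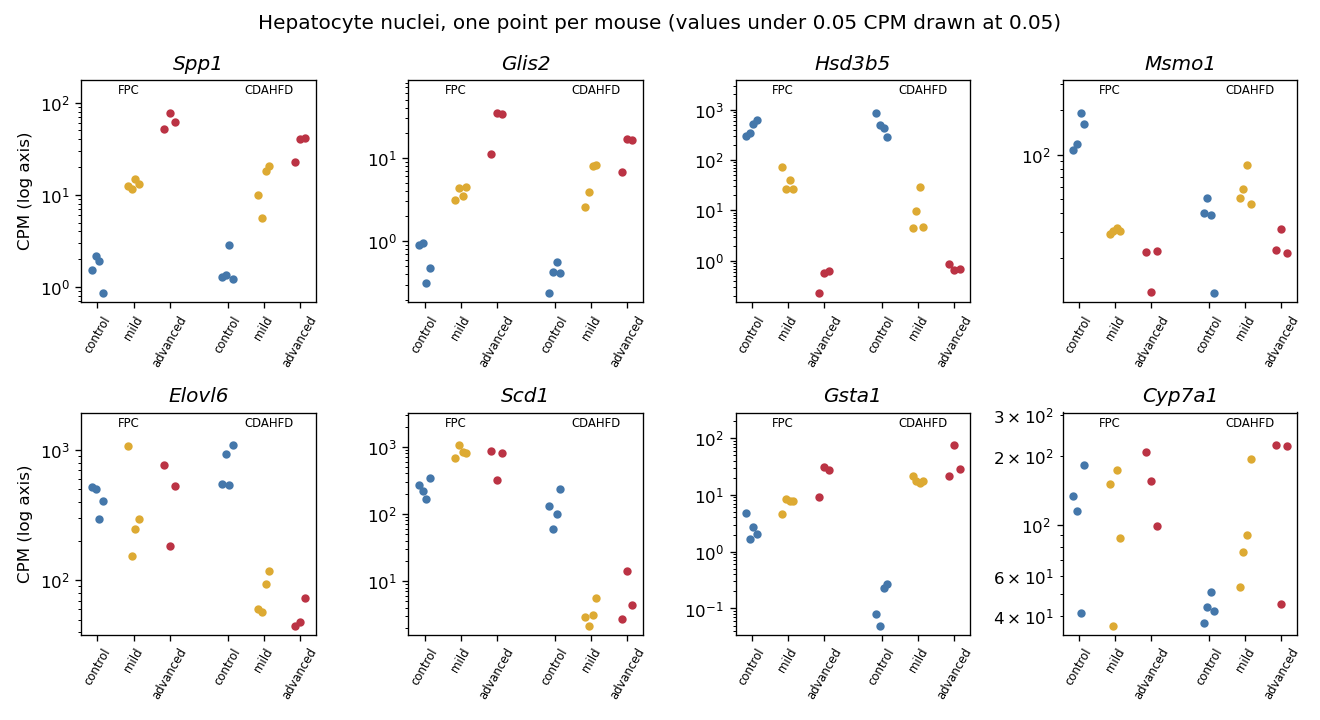
CPM of 8 genes in hepatocyte nuclei (vertical axes, CPM on a log scale) by group and diet (horizontal axes), with 1 point per mouse and values under 0.05 CPM drawn at 0.05. Spp1 reaches 63.7 CPM in advanced FPC mice, while Scd1 averages 661.9 CPM in advanced FPC and 7.11 CPM in advanced CDAHFD mice.

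Mild mice showed changes in many of these groups. Under FPC, the receptor kinase Ephb2 rose from 0.617 to 53.5 ± 17.0 CPM (6.18 ± 0.35, adjusted p = 4.4e-07) and the lipid droplet protein Cidea by 6.05 ± 0.65. The citrate transporter Slc13a2 (-6.46 ± 0.40) and Mup12 (-4.33 ± 0.61) fell. Cholesterol synthesis genes fell in 23 of 24 (median -1.25, camera adjusted p = 1.5e-12, p = 0.10 with estimated correlation; 19 after correction, median -1.16, median standard error 0.23 to 0.25). Fetal and progenitor-associated genes rose in 17 of 19 (median 2.76, 7.2e-10, p = 0.027 with estimated correlation), cell cycle genes in 19 of 20 (median 2.11, 1.9e-09, p = 0.027 with estimated correlation; 16 after correction, median 2.12, median standard error 0.36 to 0.43). Cholangiocyte markers rose in 9 of 11 (median 2.77, 7.5e-07, p = 0.11 with estimated correlation) and lipid droplet genes in 10 of 18 with 1 lower (12 and 1 over the list alone; median 1.21, 0.00055, p = 0.12 with estimated correlation). Endothelial markers rose in 13 of 18 (14 over the list alone; median 0.98, 0.00014, p = 0.32 with estimated correlation). Kupffer cell markers rose in 8 of 13 (10 over the list alone; median 1.99, 0.00072, p = 0.26 with estimated correlation). This group had the carry-over ratio of 17.0%. After the correction 0 of 3 Kupffer cell genes rose (2 of the same before; median 2.01 to 0.94, median standard error 0.32 to 1.45). Collagen and matrix genes rose in 26 of 31 before it and in 3 of 23 after it (20 of the same before; median 1.54 to 0.29, median standard error 0.29 to 1.11). Fetal genes rose in 12 of 18 after it (16 of the same before; median 2.76 to 2.81, median standard error 0.38 to 0.56) and cholangiocyte genes in 9 of 11. In all 2948 genes rose and 1519 fell, and with the correction 2430 changed.

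In mild CDAHFD mice the scaffold gene Iqgap3 (465-fold, 128 to 3840) and Gpnmb (8.17 ± 0.51, adjusted p = 6.4e-07) rose most, and Moxd1 (-9.80 ± 1.63, but -7.35 without mouse Control_9867) and Trhde (-6.28 ± 0.32) fell most. Here too Gpnmb was too low to test after the carry-over correction. Fatty acid synthesis genes fell in 12 of 15 (13 over the list alone; median -2.22, camera adjusted p = 2.2e-05, p = 0.11 with estimated correlation). The desaturase Scd1 stood at 132 ± 74.5 CPM in controls and 3.45 ± 1.5 in mild mice. Cell cycle genes rose in 19 of 20 (median 3.51, 5.3e-10, p = 0.11 with estimated correlation). Fetal and progenitor-associated genes rose in 17 of 18 (median 3.30, 3e-07, p = 0.11 with estimated correlation; 15 of 17 after correction) and cholangiocyte markers in 11 of 12 (11 with 1 lower over the list alone; median 2.88, 0.00075, p = 0.35 with estimated correlation). NF-kB targets rose in 13 of 15 (14 over the list alone; median 2.53, 4.1e-06, p = 0.12 with estimated correlation) and recruited macrophage markers in 10 of 10 (median 3.97, 1e-05, p = 0.031 with estimated correlation; 3 of 4 after correction, all 4 before, median 2.88 to 1.99, median standard error 0.29 to 0.75). Cholesterol synthesis genes rose in 5 and fell in 4 of 24 (median 0.35, 0.56). In all 3928 genes rose and 3551 fell.

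Advanced and mild mice differed by more genes under FPC than under CDAHFD. Gldn, a gene of the nodes of nerve fibres, rose from 0.503 to 46.9 ± 5.83 CPM under FPC (6.43 ± 0.70, adjusted p = 7.1e-05) and from 2.59 to 90.7 ± 10.2 CPM under CDAHFD (4.99 ± 0.74, 0.0088). Mmp7 rose (5.46 ± 0.30), and Hsd3b5 (-6.67 ± 0.58) and Sgcz (-6.56 ± 0.76) fell under FPC. The FERM domain gene Frmd5 rose (4.06 ± 0.51, 0.0026), and the sulfotransferase Sult2a8 (-3.40 ± 0.33, 0.00057) and Hsd3b5 (-4.16 ± 0.82, 0.029; 0.052 without the expression filter and up to 0.116 without mouse Advanced_9896) fell under CDAHFD. Under FPC cholangiocyte markers rose in 10 of 11 (11 over the list alone; median 2.19, camera adjusted p = 2.6e-10, p = 0.16 with estimated correlation; 9 after correction). Fetal genes rose in 14 of 19 (15 over the list alone; median 1.54, 3.7e-09, p = 0.10 with estimated correlation; 11 of 18 after correction, 14 of the same before, median 1.55 to 2.18, median standard error 0.34 to 0.49). Pericentral genes fell in 8 of 12 (11 over the list alone; median -1.53, 9.5e-07, p = 0.16 with estimated correlation). Endothelial markers fell in 11 of 18 (13 over the list alone; median -1.20, 1.9e-06, p = 0.26 with estimated correlation), beside carry-over ratios of 17.0% in mild and 9.11% in advanced mice that come from the same markers.

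Between advanced and mild CDAHFD mice cholesterol synthesis genes fell in 4 of 24 (17 over the list alone; median -1.0, camera adjusted p = 8.3e-10, p = 0.23 with estimated correlation) and bile acid genes in 6 of 19 (9 over the list alone; median -0.75, 3.5e-08, p = 0.097 with estimated correlation; 3 after correction, median -0.76, median standard error 0.29 to 0.30). Fetal genes rose in 4 of 18 (10 over the list alone; median 0.96, 3.5e-08, p = 0.13 with estimated correlation; 1 of 17 after correction, 4 of the same before, median 0.94 to 1.0, median standard error 0.36 to 0.46). Cholangiocyte markers rose in 1 of 12 (7 over the list alone; median 1.17, 6.8e-06, p = 0.25 with estimated correlation; 0 after correction, median 1.20, median standard error 0.38 to 0.40). Between advanced and mild FPC mice 1716 genes rose and 1011 fell. Between advanced and mild CDAHFD mice 173 rose and 202 fell (2725 unadjusted), with 1119 changed by DESeq2, 745 with both groups fitted alone, 60 without mouse Advanced_9896 and 309 without mouse Mild_9894.

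Whole liver nuclei, which include those of non-parenchymal cells, were compared in the same way. Col1a1, the main fibrillar collagen chain, rose from 3.16 to 70.4 ± 28.0 CPM under FPC (log2 fold change 4.05 ± 0.34, adjusted p = 1.1e-06) and by 2.51 ± 0.38 (0.00015) under CDAHFD. Trem2 rose by 5.12 ± 0.31 and 5.71 ± 0.33. Largest under FPC were the rises of Vmn2r3 (429-fold, 146 to 2080, with a log2 fold change of 8.06 that was 7.02 without mouse Advanced_6880), Mmp7 (335-fold, 114 to 1630) and Scube3 (7.01 ± 0.55) and the falls of Hsd3b5 (-9.93 ± 0.71), Mup12 (-8.69 ± 0.78) and Sult2a8 (-7.09 ± 0.25). Under CDAHFD they were those of Trim29 (at least 308-fold), Vmn2r3 (1940-fold, 662 to 9390) and the macrophage elastase Mmp12 (9.63 ± 0.28), and of Hsd3b5 (-9.81 ± 0.87), Moxd1 (-9.63 ± 1.92, but -7.07 without mouse Control_9862) and Trhde (-8.26 ± 0.27). Glis2 rose by 2.98 ± 0.27 and 1.95 ± 0.33, Elf3 by 4.27 ± 0.45 and 2.94 ± 0.35, and Spp1 by 3.89 ± 0.26 and 2.52 ± 0.25 under FPC and CDAHFD. Timd4 fell (-2.77 ± 0.46 and -3.69 ± 0.28). Timp1, an inhibitor of matrix proteases, was 36.1-fold higher (11.9 to 179) under FPC. Sox9 rose by 0.86 ± 0.33 under CDAHFD (0.039; 0.077 with both groups alone, up to 0.166 without mouse Advanced_9896), and Afp by 0.82 ± 0.32 under FPC (0.045; 0.051 with DESeq2).

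By list, collagen and matrix genes rose in 32 of 33 with 1 lower in advanced FPC whole liver (median 2.45, camera adjusted p = 2.9e-11, p = 0.11 with estimated correlation). Under CDAHFD they rose in 26 of 33 with 1 lower (median 1.34, 2.8e-06, p = 0.22 with estimated correlation). Recruited macrophage markers rose in 10 of 10 under both diets (medians 4.22 and 5.46; 1.7e-07 and 1.8e-08; 0.014 and p = 0.031 with estimated correlation). Stellate cell markers rose in 10 of 14 with 1 lower under FPC (median 1.11, 0.026, p = 0.40 with estimated correlation) and in 5 with 4 lower under CDAHFD (median 0.14, 0.80). Neutrophil markers rose in 5 of 5 under CDAHFD (median 2.67, 0.0062, p = 0.059 with estimated correlation). Hepatocyte markers fell in 18 and 19 of 22 (19 and 20 over the list alone; medians -1.22 and -1.72; adjusted p = 0.089 and 0.059 with an estimated correlation). Cholesterol synthesis fell in 24 of 24 under FPC (median -2.07, 5.6e-10, p = 0.15 with estimated correlation) and fatty acid synthesis in 15 of 15 under CDAHFD (median -2.51, 2.8e-07, p = 0.033 with estimated correlation).

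Changed genes in whole liver numbered 4428 higher and 3954 lower in advanced FPC mice against control (14129 tested) and 4194 and 3653 under CDAHFD (14098 tested). Mild mice gave 3530 and 2576, and 3901 and 3459. Advanced against mild gave 1881 and 1269 under FPC (1956 changed without mouse Advanced_6880), and 117 and 148 under CDAHFD (1953 unadjusted; 707 changed with DESeq2, 483 with both groups alone, 66 without mouse Advanced_9896). In every comparison of groups in either fraction, none of the other 34 divisions of the same mice gave as many genes (exact permutation p = 0.0286), the highest other count being 4192 where the real one was 8382.

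In advanced mice the cholangiocyte markers no longer stood lower in hepatocyte than in whole liver nuclei. Under FPC 5 of 12 were higher (median 0.37, camera adjusted p = 0.042, p = 0.52 with estimated correlation), and under CDAHFD 2 of 12 (median 0.35, 0.30). Endothelial markers stayed lower in 18 and 17 of 18 (18 and 18 over the list alone; medians -3.37 and -3.54; 0.039 and p = 0.023 with estimated correlation). Recruited macrophage markers stayed lower in 9 and 10 of 10 (medians -3.29 and -3.49). The change in advanced mice was larger in hepatocyte than in whole liver nuclei for the pericyte gene Rgs5 (interaction 3.19 ± 0.29, adjusted p = 2.3e-06) and Tmem117 (3.51 ± 0.62) under FPC. Under CDAHFD it was larger for Fhl3 (6.41 ± 1.04) and Rbm24 (5.96 ± 1.08). It was smaller for Prex1 (-2.99 ± 0.33) and Nr4a3 (-3.57 ± 0.98, 0.042; lost with the compared groups alone and without any of 5 mice, up to 0.582) under FPC. It was smaller under CDAHFD for the mesenchymal factor Prrx1 (-4.73 ± 0.38, 1.7e-07) and the osteoclast pump gene Atp6v0d2 (-3.95 ± 0.67). The list interaction was positive for cholangiocyte markers (median 1.14, 3.2e-06, p = 0.18 with estimated correlation) and fetal genes (median 1.04, 1.1e-05, p = 0.18 with estimated correlation) under FPC. Under CDAHFD it was positive for fetal (median 1.41, 4.4e-06, p = 0.12 with estimated correlation) and cell cycle genes (median 1.14, 4.4e-06, p = 0.12 with estimated correlation). The same holds for acute phase (median 0.88, 0.00011, p = 0.0075 with estimated correlation) and cholangiocyte genes (median 1.08, 0.0023, p = 0.46 with estimated correlation). Hepatocyte markers moved in the same direction. Their mean log2 ratio of hepatocyte to whole liver nuclei was 0.052 in control and 0.84 in advanced CDAHFD mice, and 0.039 and 0.36 under FPC. A positive list interaction can therefore also come from a smaller share of hepatocyte RNA in whole liver, and the list values were not tested against this.

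Genes with a fraction by disease interaction numbered 406 higher and 141 lower under FPC (1355 changed with the mouse as a block). Under CDAHFD they numbered 519 and 947 (2572 with the block, 869 without mouse Advanced_9896). The CDAHFD block pairs Control_9862 and Control_9867 as labelled, though their libraries deviate crosswise, and exchanging them raises the blocked count (given below). Which direction had more genes depended on the fit, with 733 higher and 173 lower for the compared groups alone, 662 and 638 by RLE and 973 and 909 by DESeq2. No other of 35 divisions gave as many (exact permutation p = 0.0286). Between the fractions of advanced mice, 692 and 2534 genes differed under FPC (3186 and 3235 with the block) and 2879 and 3298 under CDAHFD. With 3 pairs of libraries there are 10 divisions, too few for an exact p under 0.05.

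The diets shared most changes of advanced hepatocyte nuclei. Of 13126 genes tested under both, 2593 rose under both (1022 expected by chance) and 2018 fell under both (803 expected), while 83 changed in opposite directions, and fold changes correlated across genes (r = 0.868). Mild mice shared 2122 and 1027 (829 and 407 expected), with 76 opposite and r = 0.801. The controls of both diets were different mice.

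Lipid synthesis differed between the 2 diet studies by direct test. FPC was fed for 20 weeks and CDAHFD for 7, so diet cannot be told apart from duration or study in these differences. Cholesterol synthesis genes fell less under CDAHFD, with 10 of 24 past the test in advanced mice (16 over the list alone; median difference 0.99, camera adjusted p = 2e-08, p = 0.39 with estimated correlation). In mild mice 15 of 24 passed (20 over the list alone; median 1.29, 2.4e-12, p = 0.17 with estimated correlation). Fatty acid synthesis genes fell further under CDAHFD in 7 of 15 (median difference -1.58, 0.00089, p = 0.39 with estimated correlation; in mild mice 7, 11 over the list alone, median -1.81, 9e-07, p = 0.17 with estimated correlation). Msmo1 stood at 144.1 CPM in FPC and 35.5 CPM in CDAHFD controls and at 18.6 and 25.2 CPM in advanced mice, so for this gene the gap between the studies was wider in controls. The lipase-like gene Pnpla3 (-6.23 ± 1.11, adjusted p = 0.0026) was lower in the advanced difference and Gsta1 (5.16 ± 0.79, 0.00072) and Frmd5 (5.26 ± 1.16, 0.0083; 0.065 without mouse Control_6953) higher. Rtn4r (-8.63 ± 2.74, 0.049; 0.055 with the stricter filter) and Cd36 (2.27 ± 0.70, 0.041; 0.063 without the expression filter) stood at the threshold. In mild mice Scd1 (-7.07 ± 0.71, 2.2e-05) and Pnpla3 (-6.64 ± 1.0) were lower, and Cyp2b9 (7.06 ± 1.94, 0.027; 0.075 without mouse Control_6816) and Clec2h (5.75 ± 1.36, 0.013) higher.

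Spp1 (difference -0.92, adjusted p = 0.24), Elf3 (0.61), Glis2 (-0.30), Hnf4a (0.13) and Cyp7a1 (1.51, 0.24) did not pass a test of the difference between diets. In all 622 genes were higher and 1016 lower in the advanced difference (927 changed without mouse Advanced_6826) and 772 and 917 in the mild difference (889 without mouse Mild_9852). With the compared groups fitted alone more genes were higher than lower, 607 and 522 in the advanced and 1146 and 969 in the mild difference. Of 100 divisions of the mice within the fit, the real one included, 13 and 9 gave at least as many genes. In 11 and 6 of these most diseased mice of a diet were exchanged with its controls. That moves the disease change itself into the difference (highest other count 8040 for advanced mice), so these divisions do not show what chance gives. When mice were exchanged between the diets instead, a test chosen after seeing this, 8 and 1 of 100 did, again with the real one. For mild mice the real division was the only one, and the highest other count was 1.

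The authors' deposited table for hepatocyte nuclei held 5760, 3990 and 2631 genes with an adjusted p under 0.05 under FPC (advanced against control, mild against control, advanced against mild) and 7334, 6894 and 1004 under CDAHFD. Genes called in both that table and the present tests numbered 5040, 3128, 2144, 6708, 6342 and 321, all with the same direction, and fold changes correlated at 0.999 or higher. Both rest on the same libraries, so this is not independent support. Against controls the deposited table held more lower than higher genes. Under FPC these were 3045 and 2715 (advanced) and 2229 and 1761 (mild), and under CDAHFD 3821 and 3513, and 3644 and 3250. The present tests called more higher than lower genes there. The genes tested differed, with 11937 in both under FPC and 11850 under CDAHFD, and the cause was not tested.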

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

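The tests of other cell types, of spread, of control mice in the shared fit and of crossed libraries in this part were chosen after seeing the result, as was the exchange of mice between diets. The tests of depth and of other divisions of the mice were written before it.

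Cholangiocyte and recruited macrophage markers both rose in hepatocyte nuclei of advanced mice, and nuclei carried over without the tag could raise either. For recruited macrophage markers the values do not decide. Over the 6 advanced mice their median log2 ratio of hepatocyte to whole liver nuclei was -3.67, in the range of endothelial markers (-3.83 to -3.18), but the highest mouse stood at -2.76. That mouse, Advanced_6904, also had the highest endothelial ratio of the 6 (-3.18). With carry-over subtracted, 6 of the 10 were too low to test under each diet, while Cd9 under FPC (3.40 ± 0.21) and CDAHFD (2.02 ± 0.28), Lgals3 under FPC and Lyz2 and Itgax under CDAHFD still rose. Lgals3 also belongs to the fetal and progenitor-associated list, so its rise need not come from macrophages. Under FPC Lyz2 (adjusted p = 0.164) and Atp6v0d2 (0.271) no longer passed, and under CDAHFD Atp6v0d2 turned from 2.70 ± 0.50 to -8.12 ± 2.11 (0.0095). Values below 0 after the subtraction are set to 0, so the size of that turn is not a measured fold. For cholangiocyte markers carry-over does not account for the rise, since their lowest ratio among the same mice was -0.058. Cholangiocyte nuclei that carry the tag remain possible. With a fixed share of tagged nuclei they need a ratio that does not move with disease, and the lowest advanced mouse lay above the highest control by 0.81 under CDAHFD (SD of controls 0.20) but by 0.0034 under FPC (SD 0.45). The ratio of any tagged nuclei also rises when their share of whole liver falls, and that of hepatocyte markers rose from 0.052 to 0.84 under CDAHFD and from 0.039 to 0.36 under FPC. Relative to the hepatocyte markers of the same mouse, advanced and control ranges overlapped under both diets (gaps of -0.21 under FPC and -0.013 under CDAHFD), while the means differed by 0.64 and 0.42, over the SD of controls (0.43 and 0.25), so these values do not decide. Under CDAHFD the overlap rests on mouse Control_9867 alone, whose libraries deviate crosswise with those of another control (below). The labels do not name the cells in which the tag is made. The biological alternative, hepatocytes that take on duct genes with disease, was not separated from that by any test here.

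Advanced and mild mice differed by 2727 genes under FPC but by 375 under CDAHFD in hepatocyte nuclei. The gap was smaller with DESeq2 (3207 and 1119), with the compared groups fitted alone (2297 and 745) and in the authors' deposited table (2631 and 1004), and without mouse Advanced_9896 the CDAHFD count was 60. Lower depth of the CDAHFD libraries does not account for it, since FPC libraries thinned from 23.3 to 18.6 M counts still gave a median of 2617 genes over 20 draws (2586 to 2656). A wider spread of the compared mice does not either, with common dispersions of mild and advanced mice of 0.0383 under CDAHFD and 0.0582 under FPC. The wider spread of CDAHFD controls in the shared fit (0.0707, against 0.0355 under FPC) does not account for the whole gap, since 2297 and 745 genes remained without controls, but part of it stays open to that. Biologically, mild mice may stand closer to advanced ones under CDAHFD, where the median mild change was 77.4% of the advanced one against 59.5% under FPC. Mild and advanced changes of a diet share its controls, so the wider spread of CDAHFD controls enters both, and these shares do not decide it. In a direct test of the diet difference in advanced against mild mice, added after seeing the gap, 14 of 13808 genes passed (4 higher, 10 lower under CDAHFD). Of 2619 genes called under FPC, 2475 had the same sign under CDAHFD (94.5%), so the changes differ in number of calls more than in direction.

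Libraries of the control mice Control_9862 and Control_9867 of the CDAHFD study deviate crosswise. Their own fractions correlated at -0.227 and -0.306, while each hepatocyte library correlated with the other mouse's whole liver library at 0.889 and 0.801, which are the values an exchange of libraries needs. Of 24 assignments in this group 4 fit better than the labels (mean correlation 0.281 as labelled, 0.837 at best), and in the other 5 groups the labels fit best. Egfr is the top gene in the hepatocyte library of Control_9862 (1.80%) and the whole liver library of Control_9867 (1.87%), and Ghr in the other pair (1.22% and 1.26%). Both mice are controls, so comparisons of groups within a fraction do not depend on it, but blocked fits and the carry-over values of these mice do, and no biological explanation was tested.

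Divisions of the mice other than the real one gave fewer genes in each of the 12 comparisons of groups (1 of 35, the real one) and in both interactions (1 of 35). Fractions are paired by mouse, and only 8 divisions in controls and 4 in advanced mice part every pair as the real one does, too few to decide. The real counts were 2512 and 4444 in controls and 3226 and 6177 in advanced mice, and the highest among the other divisions of this kind was 0 in each group. Divisions that keep some pairs together (35 in controls and 10 in advanced mice in all) reached 240, 304, 19 and 6. For the differences between diets 13 of 100 (advanced) and 9 of 100 (mild) gave as many, the real division included. Most of these exchanged diseased and control mice within a diet, which moves the disease change into the difference, so they cannot decide. With mice exchanged between diets 8 of 100 (advanced) and 1 of 100 (mild, the real division alone) did. The advanced count of 1638 may therefore include chance differences between mice.

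Dixon's test marked 1 mouse far from the other 3 in 17 of 260 groups, where chance marks about 1 in 20. In whole liver, mean log2 neutrophil markers of Control_6953 were -0.27 (others -0.52 to -0.49) and hepatocyte markers of Control_10110 were 9.25 (8.71 to 8.76), and the 10 top genes of Mild_9852 took 3.69% (4.97 to 5.22). In hepatocyte nuclei, Kupffer cell markers of Control_6952 were 0.44 (0.66 to 0.70) and recruited macrophage markers of Control_10110 were -0.028 (-0.32 to -0.27). In whole liver, Elf3 was high in Control_6952 (0.372 CPM), Cyp7a1 in Mild_10102 (123 CPM), Gdf15 in Mild_9853 (13.7 CPM) and Pdgfra in Mild_6888 (19.3 CPM). In hepatocyte nuclei, Elf3 was high in Mild_6886 (1.62 CPM), Hnf4a in Control_6953 (500.5 CPM), Timp1 in Control_6816 (0.0394 CPM), Spp1 (2.82 CPM) and Clec4f (4.74 CPM) in Control_10110, and Trem2 (0.12 CPM) and Cd36 (5.58 CPM) in Control_9862. Cyp8b1 was low in hepatocyte nuclei of Control_6952 (8.64 CPM). For Timp1 and Trem2 the other 3 mice had 0 CPM, and there the test marks any mouse with a count. These marks are among the 17 and do not show that the mouse was unusual.

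Of 103 genes named for advanced against control hepatocyte nuclei, 13 differed between the diets in that comparison by the test of the difference (CDAHFD minus FPC, log2). Higher were Creb3l3 (0.70), F10 (1.01), Atf4 (1.20), Cd36 (2.27), Msmo1 (2.42), Mki67 (3.63) and Gsta1 (5.16). Lower were Elovl6 (-4.08), Cux2 (-2.75), Trhde (-2.69), Lpl (-1.95), Timp2 (-1.57) and Nr5a2 (-0.95). Pnpla3, Frmd5 and Rtn4r, named for the difference itself, are not among the 103.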

How the results depend on the processing

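Named genes kept direction and side of the threshold in 273 of 279 cases with DESeq2, 279 of 282 with RLE scaling, 276 of 282 without a filter, 270 of 273 with the stricter filter, 272 of 279 with the compared groups alone, 42 of 44 with the block, 1981 of 2071 without a mouse and 170 of 178 with the carry-over subtracted, an alternative chosen after seeing the data. Tests that leave out a mouse use edgeR's pooled spread. The cause was not tested for any change below, except that fewer mice were used in leave-one-out fits. Genes with 0 or few counts and 1.5-fold changes are where depth and spread limit the tests. In simulated data for the main comparison 7.14% of 1.5-fold changes were found. That simulation changed 200 genes, while the real comparison called 6336 under a less strict adjusted threshold, so the share does not give its sensitivity.

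Counts that moved by over 1.5 times were, for advanced against mild under CDAHFD, 375 in hepatocyte nuclei (DESeq2 1119, carry-over subtracted 227, groups alone 745, without a mouse 60 to 309) and 265 in whole liver (707 with DESeq2, 483 with groups alone, 66 to 241 without a mouse). Advanced against mild in FPC whole liver gave 3150 (1956 to 3729), and mild against control FPC hepatocyte nuclei 4467 (2430 with carry-over subtracted). With the mouse as a block, fractions gave 5767 in FPC controls (main 2512) and 6421 in FPC advanced mice (3226), and interactions 1355 (547) under FPC and 2572 (1466) under CDAHFD. The block changed no other count by as much. Among named genes it gained the calls of F2 and Serpinc1 in FPC controls, and among lists it gained 42 and lost 1 of 201. For CDAHFD controls RLE gave 2772, groups alone 2050 and the block with libraries of Control_9862 and Control_9867 exchanged, chosen after seeing the data, 8151 (main 4444). The CDAHFD interaction gave 906 with groups alone, 4243 with that exchange and 869 to 1343 without a mouse. The differences between diets gave 927 to 2045 (advanced, main 1638) and 889 to 2111 (mild, main 1689) without a mouse. Of 660 list tests 368 passed, 366 with RLE and 61 with an estimated correlation.

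Shares of higher and lower genes moved by over 10 points between settings. FPC control fractions had 193 and 2319 (stricter filter 632 and 1942, block 3069 and 2698), and FPC advanced fractions 692 and 2534 (block 3186 and 3235, groups alone 288 and 2280). CDAHFD control fractions had 2092 and 2352 (DESeq2 471 and 2592, RLE 340 and 2432, block 3712 and 2474, groups alone 129 and 1921). The CDAHFD interaction had 519 and 947 (DESeq2 973 and 909, RLE 662 and 638, groups alone 733 and 173) and the advanced difference between diets 622 and 1016 (groups alone 607 and 522). The 4611 genes shared by the diets stayed between 3231 (adjusted p under 0.01) and 5046 (DESeq2).

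Among genes named for a comparison, only some that did not pass it turned sign. Outside these, Atp6v0d2 in advanced against control CDAHFD hepatocyte nuclei passed and went from 2.70 to -8.12 with carry-over subtracted. Values below 0 are set to 0 there, so -8.12 is not a measured fold. In advanced against control FPC hepatocyte nuclei Cyp7a1 had 0.00987 with the stricter filter, 0.064 with carry-over subtracted and -0.37 to 0.32 without a mouse, and Plin2 -0.26 to 0.024. Under CDAHFD Clec4f had -0.19 to 0.68 and Plin2 -0.073 to 0.47. Plin2 in whole liver had -0.24 to 0.028 (FPC) and -0.41 to 0.15 (CDAHFD). In the difference between diets Gdf15 had -0.0105 (DESeq2), -0.0013 (no filter), -0.0077 (carry-over subtracted) and -0.39 to 0.63, Trem2 0.24 (DESeq2), 1.09 (carry-over subtracted) and -1.08 to 2.16, Pdgfra 0.18 (carry-over subtracted), Afp -1.08 to 0.041, Glis2 -0.65 to 0.0017 and Hnf4a -0.017 to 0.35.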

Other observations

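Tests of 14 gene families, taken from their symbols, were chosen after seeing the data. In advanced against control hepatocyte nuclei laminin genes, which form basement membranes, rose in 9 of 11 under both diets (1 fell; medians 2.95 and 1.75; limma camera adjusted p = 0.00024 and 0.0053, p = 0.10 and 0.30 with an estimated correlation), and in 8 after the carry-over correction (medians 2.48 and 2.62). Growth factor genes rose in 13 of 19 under FPC with 2 lower (0.00017, p = 0.032 with an estimated correlation, which no other family passed; 10 of 16 after correction and 11 of the same before, median 2.17 to 2.80) and in 10 of 18 under CDAHFD with 2 lower (0.023, p = 0.28 with an estimated correlation). Semaphorin genes, which guide axons and cells, rose in 10 of 17 with 2 lower and 9 of 16, and annexin genes in 6 of 10 with 1 lower and 8 of 10. ADAM and ADAMTS proteases rose in 19 of 31, and 16 with 4 lower (p = 0.063 and 0.26 with an estimated correlation). After the correction 11 of 29 rose under FPC (19 of the same before, median 1.25 to 1.20, median standard error 0.28 to 0.45) and 14 with 2 lower under CDAHFD (16 and 4 before, median 0.98 to 0.42). Integrin genes, receptors of the matrix, rose in 14 and 15 of 28 with 2 and 3 lower, and after the correction in 7 of 21 and 9 of 23 (medians of these genes 0.20 to 0.25 and 1.52 to 1.46). TEAD genes, partners of YAP, rose in 3 of 4 under both diets, but as a set passed under FPC alone (camera adjusted p = 0.019 and 0.14, p = 0.20 and 0.30 with an estimated correlation). Tubulin genes rose in 6 and 7 of 10 with 1 lower in each.

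Major urinary protein genes, whose copies share reads, fell in 9 and 10 of 10 (medians -5.68 and -6.07; camera adjusted p = 6.3e-06 and 3.5e-06, p = 0.17 and 0.26 with an estimated correlation). UDP-glucuronosyltransferase genes fell in 7 of 9 under both diets, and CYP2 genes in 20 of 38 with 3 higher and 19 of 36 with 8 higher (16 and 8 after correction, median -1.11 to -1.02). Genes of nuclear-encoded NADH dehydrogenase subunits fell in 18 and 24 of 35 (medians -0.48 and -0.71; 6.3e-06 and 1.9e-05, p = 0.063 and 0.28 with an estimated correlation), and after the correction in 12 and 19 (medians -0.44 and -0.68). Ribosomal protein genes rose in 6 of 70 under FPC (median 0.17, 0.31) and 36 of 70 with 1 lower under CDAHFD (median 0.45, 0.00072, p = 0.37 with an estimated correlation). Proteasome genes rose in 1 and fell in 6 of 37 under FPC (3 after correction, median -0.14 to -0.092), and 8 and 15 of 37 under CDAHFD.

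The top gene of a library took up to 3.86% of its counts (Cmss1 in whole liver of Advanced_6826).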
